A study of Mus musculus with 12 samples.

How the data were processed

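The series holds 12 RNA-seq libraries of thioglycollate-elicited peritoneal macrophages from 5-month-old mice, 3 each of wild type, miR-33 knockout, Ldlr knockout and double knockout. Per the labels' protocols, cells were collected by lavage, plated for a short time, washed to remove non-adherent cells and frozen, and total RNA was treated with DNase and depleted of ribosomal RNA before sequencing of single-end reads on an Illumina instrument. The library kit named in the labels is one for small RNAs, and the strandedness of the libraries is not given in the sources used here, so overlapping and antisense genes could not be told apart.

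The deposited values are FPKM, fragment counts scaled by transcript length and by the mapped total of the library, 1 value per gene and library, which the authors computed with Cuffdiff after quality trimming with in-house scripts and alignment with TopHat2, per the labels' protocols. The build was mm10, per the submitters' processing notes. Versions, the gene annotation and the handling of reads that map to several places are not given in the sources used here. FPKM divides by the library's total, so a few abundant RNAs move all other values of a library, and values of short RNAs and of pseudogenes with a close parent gene are uncertain.

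The table holds 23997 gene rows, of which 6283 are 0 in every library. Of the symbols, 27 were in the form of dates, and 4 of these rows share a symbol with another, so these genes are not named. By symbol, 23597 rows matched the GENCODE release vM21 annotation (GRCm38, the assembly of mm10), 22668 directly and the rest through older symbols, and positions and 3' UTR sequences were taken from there. The column names give the genotype and a number that starts at 0, while the labels number replicates from 1, so each column was tied to its group only, and libraries are called a, b and c in column order. No columns were left unmapped, and no pair of libraries was identical.

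The absolute depth is unknown. For 10178 genes with a mean FPKM under 0.1, ratios between libraries fell on ratios of whole numbers up to 6 within 0.02 on the log2 scale for 83.4% to 88.8% of values, which gave the relative depths. They set no count per gene, so no counting interval is given.

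Values were tested as log2(FPKM + 1) for the 10839 genes with a mean FPKM of at least 1 over the 12 libraries. A linear model with a mean per group was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend; 8 residual and 3.75 prior degrees of freedom), so that all groups shared an estimate of the spread. Contrasts were miR-33 knockout against WT, double knockout against Ldlr knockout, Ldlr knockout against WT, double knockout against miR-33 knockout, the miR-33 effect averaged over Ldlr genotypes, and the interaction. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 per contrast. Fold changes are on the log2(FPKM + 1) scale and understate the change of low genes. The median log2 change of all genes was between -0.01 and 0.01 in each contrast.

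Before the data were examined, 29 lists of pathway genes and cell type markers were fixed; 364 of their 379 symbols were found. Lists with at least 5 tested members were tested with limma's camera (preset correlation 0.01, and again with the correlation estimated), adjusted over the 21 lists tested per contrast, and members were also adjusted over the list alone. A list is said to rise or fall where the camera test with the preset correlation passed. Apart from members shared between lists, some markers of other cell types are also expressed by macrophages.

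Genes named in the text follow a rule fixed at the same time: Srebf2, Ldlr, Abca1 and Abcg1 always; the 8 largest rises and falls among called genes whose groups do not overlap; up to 4 members of each called list by smallest p, and called members of other lists; and the 5 smallest p in a direction with fewer than 5 calls. Seed matches to miR-33 were searched in annotated 3' UTRs (7-mer and 8-mer sites), and calls within 10 Mb of Srebf2 or Ldlr were compared with calls elsewhere by Fisher's exact test. The smallest p of an exact permutation test of 3 against 3 libraries is 0.1, so no such test was used for single genes.

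The procedure was tested on simulated data with the spread of each gene in the real libraries. Genes were drawn independently and all libraries varied alike, so correlated genes and uneven libraries were not covered. In a test of the lists with 1 list raised, 1 of the 20 other lists was called too. With 100 genes changed by log2 1 and 100 by 0.5 among 10839, between 84% and 92% and between 25% and 69% were recovered for the 5 contrasts other than the interaction, with 3 to 9 false calls. Other settings fixed at the same time were pseudocounts of 0.1 and 5, no filter and a minimum mean FPKM of 5, median-of-ratios scaling and quantile normalization, no mean-variance trend, only the groups compared, an estimated correlation, 8-mer sites alone, a window of 5 Mb, and each library left out in turn. A stromal marker score as a covariate, leaving out double knockout libraries a and b together, array weights, and the number in the column names as a block were added after seeing the data. A block by the replicate numbers of the labels had been planned, but columns were not tied to these numbers. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.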

Results

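RNA abundance was measured in 12 libraries of thioglycollate-elicited peritoneal macrophages, which are phagocytes drawn into the abdominal cavity by an irritant broth and kept for their adherence to plastic. The mice were 5-month-old C57BL/6 animals of 4 genotypes, with 3 libraries each: wild type (WT), miR-33 knockout, Ldlr knockout and the double knockout that lacked both. miR-33 is a microRNA known to repress the cholesterol exporter Abca1, and Ldlr is the receptor that takes up low-density lipoprotein. The series title contrasts normal with hyperlipidemic mice, and blood lipids were not analysed here. The labels did not say that the 3 libraries of a group came from separate animals, so p-values measured only the spread between these libraries, which may be technical.

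Values were FPKM, without counts, and the absolute depth was unknown. Relative depth, recovered from the steps of very low values, lay between 69.1% and 100% of that of the deepest library. The FPKM of a library summed to between 507219 and 665395, of which the non-coding RNAs Rpph1 and Rmrp took between 10.5% and 18.7%. Pearson's r between libraries of a group, across genes, was lowest in the double knockout (0.961 to 0.973) and highest in WT (0.978 to 0.984). Libraries are called a, b and c within each group in the order of the table. On the first principal component double knockout libraries a (-29.2) and b (-45.5) stood apart from the other 10, which lay between -9.76 and 16.3.

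The targeted genes were examined first. Mir33 (chromosome 15, 82198122 to 82198190, mm10) lies inside Srebf2 (chromosome 15, 82147181 to 82205379), the gene of a master regulator of cholesterol synthesis, and was listed at 0 in all 12 libraries. Srebf2 was at 20.3 ± 1.18 FPKM in WT, 17.9 ± 2.39 in the libraries labelled miR-33 knockout, 15.1 ± 1.07 in those labelled Ldlr knockout and 16.6 ± 3.76 in those labelled double knockout (SD, n = 3 each), and passed no test. Ldlr (chromosome 9, 21723483 to 21749919) was present in every library, at 41.1 ± 0.872 FPKM in WT, 38.7 ± 1.25 in miR-33 knockout, 31.3 ± 0.782 in Ldlr knockout and 52.5 ± 8.91 in double knockout libraries (SD, n = 3 each). A gene-level value does not show whether a transcript carries a targeted exon, so neither gene checked the labels. All group names below are therefore names of libraries as labelled.

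**Figure D1:**
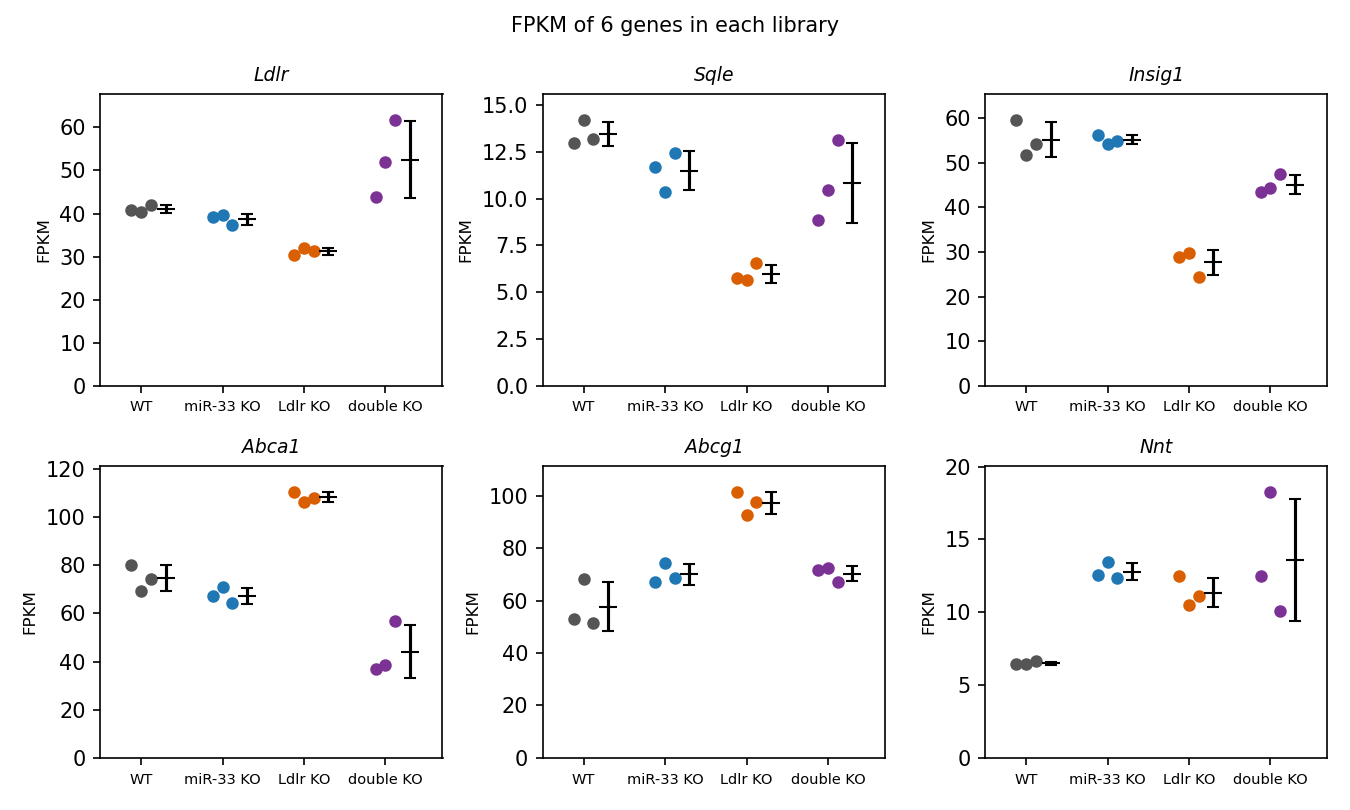
FPKM of Ldlr, Sqle, Insig1, Abca1, Abcg1 and Nnt on linear axes from 0, with a point for each of the 3 libraries of a group and a bar for the group's mean and SD. Ldlr lay at 43.9 to 61.7 FPKM in the double knockout and at 30.4 to 32.0 in the Ldlr knockout, and Nnt lay at 6.42 to 6.62 in WT and at 10.1 or more in the other 9 libraries.

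With Ldlr intact, no single gene passed the test between libraries labelled miR-33 knockout and WT. The lowest adjusted p belonged to Des, the muscle and mesenchymal intermediate filament desmin, at 0.529 ± 0.314 against 2.33 ± 0.187 FPKM in WT (SD, n = 3; log2 change -1.14, SE 0.16, adjusted p = 0.122). Il4ra, the receptor chain for interleukin 4, was at 13.8 ± 1.105 against 20.2 ± 1.48 FPKM (log2 change -0.52, adjusted p = 0.3001). The mitochondrial transhydrogenase Nnt was at 12.8 ± 0.604 against 6.50 ± 0.103 FPKM (0.88, adjusted p = 0.345). Abca1 (chromosome 4, 53030787 to 53159895) was at 67.4 ± 3.31 against 74.6 ± 5.46 FPKM, a log2 change of -0.14 (SE 0.14). Abcg1, another sterol exporter (chromosome 17, 31057675 to 31117988), was at 70.0 ± 3.9998 against 57.7 ± 9.25 FPKM (0.28, SE 0.11); the adjusted p of both was 1. Of the 20 measured members of the list of miR-33 targets, 10 were higher and none was called over all genes or adjusted over the list alone.

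As a group, fibroblast markers fell in the miR-33 knockout, with a median log2 change of -1.46 over 6 measured members (limma camera, adjusted p = 1.56e-15). None of the 6 was called over all genes, and all 6 were lower when adjusted over the list alone. The list's call was lost with an estimated correlation (adjusted p = 0.110 with an estimated correlation). Interferon response genes (median -0.25, 22 of 23 lower, adjusted p = 9.48e-06) and replication histones (median -0.27, adjusted p = 0.0160) were also lower as lists, with 0 members called over all genes and 0 adjusted over the list alone. Both calls were lost with an estimated correlation (adjusted p = 0.926 with an estimated correlation for each) and with the stromal marker score as a covariate (medians 0.16 and -0.161).

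Across all genes the test was limma's moderated test on log2(FPKM + 1), and 0 of 10839 genes passed, with 406 at an unadjusted p under 0.05 where 542 would be expected by chance. In simulated data with 100 genes changed by log2 1 and 100 by 0.5, 89% and 43% of them were recovered, in that order. These shares hold for that number of changed genes and for libraries that vary alike. They do not show that few genes changed here. The test called 21 genes without miR-33 knockout library a, 5 without double knockout library c, and 1 or 2 without double knockout library a or b, Ldlr knockout library c or WT library a. It called 7 in a fit of these 6 libraries alone and 7 without double knockout libraries a and b, a choice made after seeing the data.

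**Figure D2:**
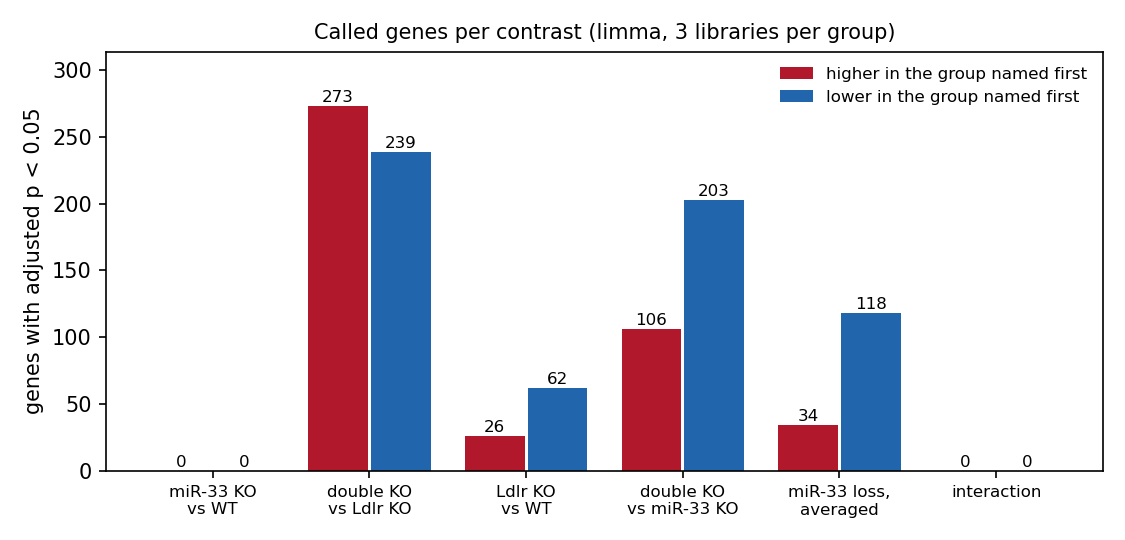
Number of genes with a limma adjusted p under 0.05 in each of the 6 contrasts, with separate bars for genes higher and lower in the group named first (for the averaged contrast, on miR-33 loss). The double knockout against the Ldlr knockout gave 273 higher and 239 lower genes, and the miR-33 knockout against WT gave 0.

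Without Ldlr, loss of miR-33 went with more RNA of cholesterol synthesis enzymes and less of Abca1. In libraries labelled double knockout, compared with those labelled Ldlr knockout, 15 of 22 measured cholesterol synthesis genes rose, 18 adjusted over the list alone, and none fell. Sc5d, a late enzyme of sterol synthesis, rose from 22.3 ± 1.72 to 39.7 ± 3.73 FPKM (SD, n = 3; log2 change 0.80, SE 0.10, adjusted p = 0.00118). Fdps, which makes farnesyl pyrophosphate, rose from 19.8 ± 0.898 to 37.9 ± 3.46 (0.90, adjusted p = 0.00214). Insig1, a sterol sensor (chromosome 5, 28071363 to 28078662), rose from 27.7 ± 2.79 to 45.1 ± 2.14 FPKM (0.69, adjusted p = 0.00186). Ldlr RNA, which responds to the same sterol-regulated factor, also rose (0.72, adjusted p = 0.00328). The list had a median log2 change of 0.57 (camera, adjusted p = 3.53e-13; adjusted p = 0.0480 with an estimated correlation) and kept its call in all 25 alternatives run for it, among them those without double knockout libraries a and b (median 0.69), with the stromal score as a covariate and with array weights.

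Abca1 fell from 108 ± 2.07 FPKM in Ldlr knockout to 44.1 ± 10.9 in double knockout libraries (SD, n = 3; log2 change -1.30, SE 0.14, adjusted p = 0.00102), with every double knockout library below every other. Of 24 alternatives for Abca1 (adjusted p from 1.63e-05 to 1) only the stromal score as a covariate ended the call, at a log2 change of -0.91 with a wider SE of 0.39. Abcg1 fell from 97.2 ± 4.30 to 70.2 ± 2.91 FPKM (-0.46, adjusted p = 0.0376), a call that was lost in 11 of 24 alternatives (adjusted p from 0.0146 to 1), among them those without double knockout library a or b or any Ldlr knockout library. Both are on the list of miR-33 targets, of whose 20 members 2 fell and 0 rose over all genes and adjusted over the list alone (median -0.003, adjusted p = 0.246). Among 16 targets of the sterol-activated receptor LXR, 3 fell (4 adjusted over the list alone), including Arl4c (-0.57, adjusted p = 0.00778), and the list was not called (adjusted p = 0.331). Both lists were called as lower without double knockout libraries a and b (medians -0.0889 for miR-33 targets and -0.105 for LXR targets) and with the stromal score as a covariate (-0.118 and -0.240).

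Transcripts of other cell types differed in the same comparison. All 6 measured fibroblast markers fell, over all genes and adjusted over the list alone, with a median of -2.77 (adjusted p = 1.78e-10; adjusted p = 0.162 with an estimated correlation). Col1a2, a chain of type I collagen (chromosome 6, 4504814 to 4541544), fell from 21.7 ± 3.14 to 1.47 ± 0.809 FPKM (-3.25, SE 0.39, adjusted p = 0.00114). Sparc (-2.86), Clu (-2.96) and Mgp (-2.63) were also among the 8 largest falls. Of 8 B cell markers 4 rose, and 7 adjusted over the list alone, with Cd79b, a chain of the B cell receptor complex, at 8.42 ± 4.89 against 1.23 ± 0.405 FPKM (1.96, adjusted p = 0.00716). The B cell list had a median of 1.04 (adjusted p = 1.10e-05; adjusted p = 0.184 with an estimated correlation), and with the stromal score as a covariate it was 0.37 and not called. Of 9 markers of resident peritoneal macrophages 3 fell (5 adjusted over the list alone), with Gata6, their lineage factor, at -1.21 and Serpinb2 at -1.86 (list median -0.69, adjusted p = 0.00960; adjusted p = 0.522 with an estimated correlation). The 10 general macrophage markers were not called (median 0.071, adjusted p = 0.485).

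Inflammatory genes were lower in the double knockout. Of 16 inflammatory activation genes 3 fell (8 adjusted over the list alone), among them the monocyte chemokine Ccl2, from 28.6 ± 0.120 to 9.55 ± 2.85 FPKM (-1.52, adjusted p = 0.00260). Ptgs2, the inducible cyclooxygenase, fell as well (-1.39, adjusted p = 0.0216). The list fell as a whole (median -0.93, adjusted p = 1.10e-05; adjusted p = 0.522 with an estimated correlation). Without double knockout libraries a and b its median was -0.0512 and the call ended, as it did with the stromal score as a covariate (0.00732). The interferon list was lower (median -0.38, 0 members called over all genes and 0 adjusted over the list alone, adjusted p = 0.00120; adjusted p = 0.555 with an estimated correlation). Its median was 0.0699 without libraries a and b and 0.51 with the stromal score as a covariate, a rise that was called. Fatty acid oxidation genes (median 0.23, adjusted p = 0.0133; adjusted p = 0.522 with an estimated correlation) rose as a list with 0 members called over all genes and 0 adjusted over the list alone, a call lost with the stromal score as a covariate (0.209). Replication histones also rose (median 0.45, adjusted p = 0.00949; adjusted p = 0.555 with an estimated correlation), with 1 member called over all genes and 1 adjusted over the list alone.

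In all, 512 genes passed in this comparison, 273 higher and 239 lower (limma). Leaving out a library moved the count by over 1.5 times for all but WT library a. It was 163, 286 and 1984 without double knockout a, b and c, 116, 176 and 272 without Ldlr knockout a, b and c. It was 295 and 269 without WT b and c, and 336, 304 and 908 without miR-33 knockout a, b and c. It was 13 without double knockout libraries a and b, 0 with the stromal score as a covariate, 916 with no filter on low values, 270 at a mean FPKM of at least 5 and 128 in a fit of these 6 libraries alone.

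**Figure D3:**
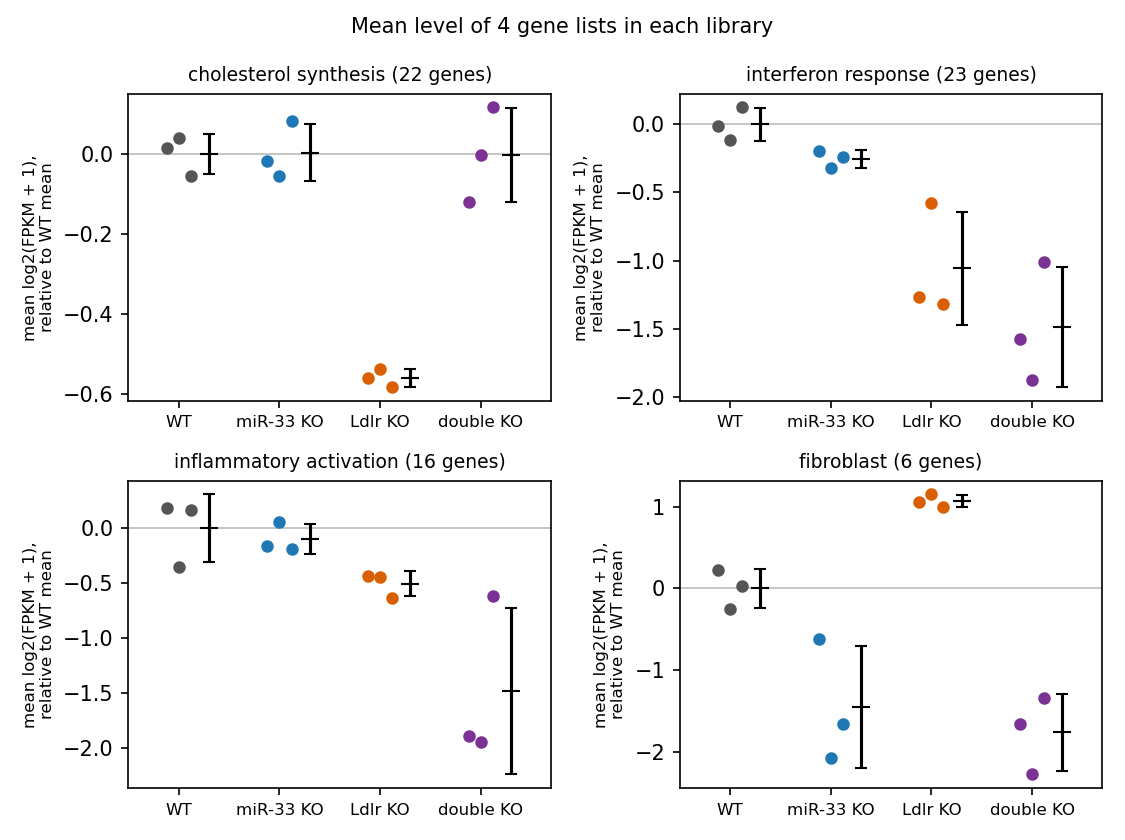
Mean log2(FPKM + 1) of the measured members of 4 gene lists in each library, relative to the WT mean, with a point per library and a bar for the group's mean and SD. Cholesterol synthesis genes lay between -0.58 and -0.54 in the 3 Ldlr knockout libraries and between -0.12 and 0.12 in the other 9, and double knockout libraries a and b lay lowest for inflammatory activation.

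With miR-33 present, libraries labelled Ldlr knockout had less RNA of cholesterol synthesis and interferon response genes than WT. Of 22 cholesterol synthesis genes 11 fell (17 adjusted over the list alone), with Sqle, the squalene epoxidase (chromosome 15, 59315077 to 59331192), down from 13.4 ± 0.655 to 5.99 ± 0.477 FPKM (SD, n = 3; log2 change -1.05, SE 0.12, adjusted p = 0.0114). Insig1 fell from 55.2 ± 3.96 to 27.7 ± 2.79 (-0.97, SE 0.09, adjusted p = 0.00238). The list had a median of -0.56 (camera, adjusted p = 8.57e-16; adjusted p = 0.0293 with an estimated correlation). Of 23 interferon response genes 7 fell (21 adjusted over the list alone), with a median of -1.08 (adjusted p = 9.28e-19; adjusted p = 0.183 with an estimated correlation). Stat1, the transcription factor of the response, fell from 37.9 ± 2.82 to 20.9 ± 3.73 FPKM (-0.84, adjusted p = 0.0132), Xaf1 changed by -1.14 (adjusted p = 0.0114), and the receptor chaperone Rtp4 by -1.71 (adjusted p = 0.0434). The interferon fall was uneven, with a mean list level relative to WT of -1.27, -0.58 and -1.32 in Ldlr knockout libraries a, b and c.

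Abcg1 rose from 57.7 ± 9.25 to 97.2 ± 4.30 FPKM in the Ldlr knockout (0.75, SE 0.11, adjusted p = 0.0132), and Abca1 was at 108 ± 2.07 against 74.6 ± 5.46 FPKM (0.53, adjusted p = 0.0913). Of 16 LXR targets 1 rose (6 adjusted over the list alone), with a list median of 0.28 (adjusted p = 5.40e-04; adjusted p = 0.0708 with an estimated correlation). The 20 miR-33 targets, which share members such as Abca1 and Abcg1 with that list, rose as a list, with a median of 0.12 (1 called, 2 adjusted over the list alone; adjusted p = 0.0356; adjusted p = 0.183 with an estimated correlation). Fibroblast markers rose as a list (median 1.102, adjusted p = 7.43e-05; adjusted p = 0.346 with an estimated correlation), 1 of 6 over all genes and 5 adjusted over the list alone, with Col1a1 at 1.43 (adjusted p = 0.0407). Inflammatory activation (-0.51, adjusted p = 0.00403), endoplasmic reticulum stress (-0.16, 0.00780), replication histones (-0.56, 7.43e-05) and lysosome and autophagy (-0.15, 0.0356) fell as lists, with 0, 1, 0 and 0 members called over all genes and 0, 1, 4 and 0 adjusted over the list alone. With an estimated correlation the adjusted p of these 4 lists was 0.602, 0.557, 0.506 and 0.588, and the lysosome median was 0.0794 after quantile normalization.

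In total 88 genes passed between Ldlr knockout and WT (limma), 26 higher and 62 lower. The count was 1 and 4 without Ldlr knockout libraries a and c, 2, 7 and 1 without WT libraries a, b and c. It was 55, 37 and 168 without miR-33 knockout libraries a, b and c, and 353 and 366 without double knockout libraries b and c. It was 707 without double knockout libraries a and b, 0 with the stromal score as a covariate, 174 with no filter on low values and 1158 in a fit of these 6 libraries alone.

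Without miR-33, libraries labelled double knockout had less RNA of interferon response and inflammatory activation genes than those labelled miR-33 knockout. Of 23 interferon response genes 19 fell over all genes and all 23 adjusted over the list alone, with a median of -1.02 (camera, adjusted p = 4.59e-18; adjusted p = 0.455 with an estimated correlation). Ifit1 fell from 19.4 ± 1.03 to 3.74 ± 3.10 FPKM (SD, n = 3; -2.29, SE 0.34, adjusted p = 0.0392) and Rsad2, the antiviral protein viperin, from 47.7 ± 5.79 to 13.2 ± 8.88 (-1.95, adjusted p = 0.0392). Of 16 inflammatory activation genes 7 fell (14 fell and 1 rose adjusted over the list alone), with the chemokines Ccl5 at -2.36 and Cxcl10 at -1.62 (list median -1.17, adjusted p = 1.75e-08; adjusted p = 0.455 with an estimated correlation). This fall was largest in the 2 double knockout libraries that stood apart: the mean level of the list relative to WT was -1.89, -1.95 and -0.62 in libraries a, b and c. Without a and b the median was -0.61 and the list was still called, and the interferon median was -0.77, also called. Irg1, which makes the antimicrobial metabolite itaconate (chromosome 14, 103046977 to 103056573), was at 4.16, 7.996 and 102 FPKM in double knockout libraries a, b and c against 189.6 ± 20.5 in miR-33 knockout libraries (-3.49, adjusted p = 0.0454).

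Genes that rose in this comparison included Apoe, the apolipoprotein secreted by macrophages, from 3185 ± 360.2 to 6864 ± 2293 FPKM (1.06, adjusted p = 0.0435), the peroxisomal fatty acid transporter Abcd2 (1.27) and Card11, a lymphocyte signalling scaffold (1.21). Abca1 fell (-0.63, adjusted p = 0.0444), and Abcg1 was at a log2 change of 0.01 (adjusted p = 0.980). Cholesterol synthesis genes were not called as a list (median -0.004, adjusted p = 0.936), except as higher without double knockout libraries a and b (0.0891). The B cell list rose (3 of 8 members, 5 adjusted over the list alone; median 0.67, adjusted p = 1.84e-04; adjusted p = 0.455 with an estimated correlation). Of 13 endoplasmic reticulum stress genes 2 fell, including the asparagine synthetase Asns at -1.20, while 6 fell and 1 rose adjusted over the list alone. That list fell (median -0.33, adjusted p = 0.0122; adjusted p = 0.733 with an estimated correlation), and its call ended without double knockout libraries a and b (-0.0810). Fibroblast markers were not called (median -0.28, adjusted p = 0.508). Small non-coding RNAs made up 6 of the 8 largest falls together with 1 pseudogene. Mir703 was listed at 0 in all 3 double knockout libraries and in Ldlr knockout library c, against 98.9, 108 and 167 FPKM in the miR-33 knockout. Snora70 lay at 148, 6.54 and 197 FPKM in the double knockout and 2909, 2186 and 3492 in the miR-33 knockout.

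This comparison gave 309 called genes, 106 higher and 203 lower (limma), the smallest adjusted p being 0.0321. The count moved by over 1.5 times on leaving out any library. It was 0 without double knockout a or b, Ldlr knockout a, WT a or c, or miR-33 knockout a or b. It was 1 without WT b, 4 without miR-33 knockout c, 32 and 131 without Ldlr knockout c and b, and 2277 without double knockout c. It was 2 without double knockout libraries a and b, 0 with the stromal score as a covariate, 0 with no filter on low values, 187 with no mean-variance trend and 5 in a fit of these 6 libraries alone.

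The comparisons of Ldlr loss with and without miR-33 share no library. They had 22 genes in common that fell, where 1.16 would be expected of independent lists (Fisher's exact test, two-sided, p = 5.58e-23), and 3 that rose, where 0.254 would be expected (p = 0.00201). In both comparisons the spread of each gene came from the same fit of all libraries. Interferon response genes also moved together within groups (estimated correlation 0.685). The Fisher p-values therefore do not measure how often chance gives such an overlap. The genes that fell in both included the interferon-induced genes Usp18, Stat1, Zbp1, Xaf1, Rtp4, Trex1 and Oas1g, and those that rose were Calcoco1, Fam214a and Kif3a, of which Calcoco1 and Kif3a were chosen after their values were seen. The number of shared genes, 25, was 0 without any 1 of 10 libraries (double knockout a or b, Ldlr knockout a or c, and each WT and miR-33 knockout library), 24 without Ldlr knockout b and 218 without double knockout c. The pair of comparisons of miR-33 loss, which also share no library, had 0 called genes in common, since 0 passed with Ldlr intact. Their log2 changes correlated at r = 0.160 (Spearman 0.305) across 10839 genes, which are not independent replicates.

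Averaged over both Ldlr genotypes, libraries labelled as lacking miR-33 differed from those with it in 152 genes, 34 higher and 118 lower (limma). All 6 fibroblast markers fell (median -2.07, adjusted p = 3.44e-13; adjusted p = 0.0852 with an estimated correlation), as did Abca1 (-0.72, SE 0.10, adjusted p = 0.00187) and Il4ra (-0.43, SE 0.06, adjusted p = 0.00313). Il4ra was at 19.3 ± 0.842 FPKM in Ldlr knockout and 15.1 ± 0.941 in double knockout libraries (SD, n = 3). Of 22 cholesterol synthesis genes 6 rose (16 adjusted over the list alone; median 0.28, adjusted p = 2.02e-10; adjusted p = 0.0852 with an estimated correlation). Among single genes Rps4l, Gins4 and Zfp764 rose by 0.71, 0.39 and 0.45; Rps4l is annotated as a transcribed processed pseudogene and may share reads with its parent gene. Inflammatory activation (-0.48, adjusted p = 1.28e-05), interferon response (-0.26, 6.31e-06) and resident peritoneal macrophage genes (-0.30, 0.0119) fell as lists, and fatty acid oxidation (0.14, 0.0124) and B cell genes (0.55, 1.42e-04) rose. In that order 2, 0, 2, 0 and 0 members were called over all genes and 3, 0, 4, 0 and 6 adjusted over the list alone. These 5 calls were lost with an estimated correlation (adjusted p = 0.326 with an estimated correlation for B cell genes and 0.553 for the other 4). With the stromal score as a covariate the inflammatory median was 0.24 and not called, the interferon median was 0.43, a rise that was called, and the other 3 lists were not called. Without double knockout libraries a and b the inflammatory and interferon lists were not called, at 0.00852 and -0.0996. The count was 1051 without double knockout library c and 100 without Ldlr knockout library a. It was 86 without double knockout libraries a and b, 0 with the stromal score as a covariate, 521 with no filter on low values and 38 among genes with a mean FPKM of at least 5.

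The interaction, the miR-33 effect without Ldlr minus that with Ldlr, was called for 0 single genes (limma; 1154 at an unadjusted p under 0.05, where 542 would be expected). It was positive for 21 of 22 cholesterol synthesis genes, with a median of 0.605 (camera, adjusted p = 8.76e-16; adjusted p = 0.0277 with an estimated correlation) and 15 members called adjusted over the list alone. For Abca1 it was -1.16 (SE 0.19, adjusted p = 0.166), for Ldlr 0.80 (adjusted p = 0.191), for Sqle 0.96 (adjusted p = 0.171) and for Gdf3, a growth factor of the transforming growth factor beta family, 1.62 (adjusted p = 0.166). In simulated data with 100 genes changed by log2 1 and 100 by 0.5, the interaction recovered 52% and 7% of them, in that order. The limits given above for simulated data hold here too. The count was 306 and 6 without double knockout libraries c and a, 3 without Ldlr knockout library c, 1 without WT library a, and 7 without double knockout libraries a and b.

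Genes with a seed match to miR-33 in the 3' UTR were compared with the rest, since loss of a microRNA can raise its direct targets. Of 10253 measured genes with an annotated 3' UTR, 1595 held a match. Their median log2 change, less that of genes matched on UTR length, was -8.62e-05 in the miR-33 knockout with Ldlr and 0.02 in the double knockout against the Ldlr knockout (limma camera, adjusted p = 0.381 and 0.325). The camera test pointed down in both, against the sign of the length-matched value in the second. Among 419 other 7-mers of the same base composition, the main 7-mer lay at the 31.5th and 78.5th percentile. Abca1 and Abcg1 each hold 2 such sites in 3' UTRs of 3156 and 3703 bases.

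Calls near the targeted loci were compared with calls elsewhere. Within 10 Mb of Srebf2, 7 of 181 genes passed in the double knockout against the Ldlr knockout (3.87%, against 4.76% elsewhere; Fisher's exact test, two-sided, p = 0.724). Within 10 Mb of Ldlr, 1 of 88 genes passed in each comparison of Ldlr loss (Kank2 against WT and Ppan against the miR-33 knockout, both chosen after their values were seen; Fisher's exact test, p = 0.517 and 0.522). Without double knockout library c the enrichment near Ldlr in the comparison with WT passed (odds ratio 2.48, p = 0.0299 by Fisher's exact test).

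Lists of fatty acid synthesis, lipid uptake and storage, alternative activation, cell cycle, immediate early, heat shock, macrophage, monocyte and neutrophil genes were called in none of the 6 contrasts (camera, at the main settings). The lowest adjusted p among them was 0.156, for fatty acid synthesis in the interaction (median 0.16). Some were called under alternatives chosen after seeing the data. Alternative activation was lower in double against Ldlr knockout with the stromal score as a covariate (-0.398, camera, adjusted p = 0.0319). Without double knockout libraries a and b its median there was -0.280, and that of fatty acid synthesis in double against miR-33 knockout was 0.181. Lists with fewer than 5 measured members were not tested. For these, mean levels relative to WT on the log2 scale in the double knockout were -0.46 ± 0.48 for 2 dendritic cell genes, 0.58 ± 0.18 for 1 eosinophil gene and -0.19 ± 0.67 for 4 mast cell genes (SD, n = 3). They were -0.16 ± 0.38 for 1 T and NK cell gene, -1.11 ± 0.37 for 2 mesothelial cell genes and -0.06 ± 1.16 for 3 erythroid genes (SD, n = 3). The eosinophil gene, Siglec5, was at 4.68 ± 0.741 FPKM in the double knockout, higher than in the Ldlr knockout (2.39 ± 0.225; log2 change 0.74, adjusted p = 0.00980) and the miR-33 knockout (2.75 ± 0.414; 0.60, adjusted p = 0.0432). No adipocyte marker reached the filter, and mitochondrial transcripts were not analysed here.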

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

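The tests of marker correlation, the tests on Abca1 with the stromal score and the run over all 200 splits were chosen only after the result was seen, and the stromal covariate, array weights and leaving out double knockout libraries a and b were chosen after seeing the data; the other tests in this part were set before their results were seen.

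The miR-33 effect differed between Ldlr genotypes for 6 gene lists by the interaction test (camera). For cholesterol synthesis genes the interaction had a median of 0.605 (adjusted p = 8.76e-16, and 0.0277 with an estimated correlation). The other 5 calls were lost with an estimated correlation. They were fibroblast markers (-1.35; adjusted p = 0.425 with an estimated correlation), B cell markers (0.99; 0.207), inflammatory activation (-0.79), replication histones (0.57) and resident peritoneal macrophage markers (-0.44), each of the last 3 with an adjusted p of 0.532 with an estimated correlation. The inflammatory value was -0.0138 without double knockout libraries a and b and -0.348 with the stromal score as a covariate, and was called in neither. The resident macrophage call also ended without double knockout libraries a and b (-0.159) and with array weights (-0.487), a pseudocount of 5 (-0.323) or no filter on low values (-0.437). It ended as well without double knockout library b (-0.318), Ldlr knockout library a (-0.402) or c (-0.259), WT library b (-0.294) or miR-33 knockout library c (-0.398).

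Genes under the filter on low values, which the comparisons did not use, held calls when the filter was removed. They numbered 2 for miR-33 knockout against WT (Cited1 and Col5a3), 415 for double knockout against Ldlr knockout, 84 for Ldlr knockout against WT, 321 for the averaged miR-33 effect and 1 (Adcyap1r1) for the interaction, of 6875 genes under the filter; these 3 names were chosen after their values were seen.

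Fibroblast markers were lower in libraries without miR-33. Scaling between libraries is argued against, since in the averaged contrast the median change was 0.007 for all genes and -2.07 for the markers. Median-of-ratios scaling could therefore move the markers little, and gave a median of -2.09 (members from -2.49 to -1.78). A varying share of stromal cells in the harvest is a candidate explanation: residuals of the markers around group means correlated at 0.815 on average over pairs of genes (0.446 to 0.972). Levels were low, with Col1a2 at 21.7 FPKM and Dcn at 20.6 FPKM in the Ldlr knockout, where they were highest. A fall of these transcripts within macrophages cannot be told apart from this, since collagens and the other markers moved together (mean residual correlation 0.818), and the genotype itself may set the share of such cells.

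Cholesterol synthesis genes were higher and Abca1 lower on miR-33 loss without Ldlr. With the stromal score as a covariate the median interaction of the cholesterol synthesis genes did not shrink. It was 0.61 (0.6127, quartiles over genes 0.37 and 0.88) against 0.605 without the score. This does not decide whether the stromal share was a cause of the cholesterol synthesis part. The slope of the score came only from differences within groups and was carried over larger ones between groups, and the median has no SE. For Abca1 the stromal share is argued against as the whole cause of the interaction, but only if the slope within groups also holds between them. That interaction was -1.16 (SE 0.19) without and -0.97 (-0.9677, SE 0.26, limma, unadjusted p = 0.00371) with the score, though called over all genes in neither fit. For the change of Abca1 between double and Ldlr knockout it stays open: this was -1.30 (SE 0.14) without and -0.91 (-0.9111, SE 0.39) with the score, and the call ended as the change shrank and the SE widened. A single divergent double knockout library is argued against for the cholesterol synthesis part, since the lowest median interaction with 1 of the 3 left out was 0.61 (0.6112). That test did not cover Abca1. The mean level of the synthesis genes relative to WT was -0.12, -0.004 and 0.12 in double knockout libraries a, b and c. It was -0.56, -0.54 and -0.58 in those of the Ldlr knockout. The Ldlr knockout was thus the group that stood apart, and leaving out a double knockout library says nothing about it. A difference in the cells' sterol load could give both parts, as sterols lower synthesis genes and raise Abca1. Levels against the miR-33 knockout do not decide whether it was the whole cause of the low Abca1. Cholesterol synthesis genes were not called between double and miR-33 knockout (median -0.004, camera, adjusted p = 0.936), which does not show equal levels. Without double knockout libraries a and b their median was 0.0891, the direction that a lower sterol load would give. Abca1 was lower there in the double knockout (-0.63, SE 0.14, limma, adjusted p = 0.0444). That call ended with the stromal score as a covariate (-0.58, SE 0.14). It also ended without double knockout library a or b, Ldlr knockout library a, WT library a or c, or miR-33 knockout library a or b. As a part of the cause, sterol load stays open as well, because the value below does not exceed its spread. Between libraries of a group, Abca1 correlated with the cholesterol synthesis score at r = 0.560 (exact permutation within groups, p = 0.517; Spearman 0.175, exact permutation p = 0.711), and r was -0.41 without the 2 libraries farthest from the median. The biological explanation by genotype stays a hypothesis, since the libraries of a group share it with everything else that differed between the groups.

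For other splits of the libraries, the 10 splits of 3 against 3 are too few for a share under 0.05. Double knockout against Ldlr knockout gave 512 genes and at most 0 in other splits (1 of 10 as large), Ldlr knockout against WT 88 and at most 0 (1 of 10), double knockout against miR-33 knockout 309 and at most 124 (1 of 10), and miR-33 knockout against WT 0 and at most 1. The split with 124 exchanged library c of each group. A count of 0 is reached by every split, so the splits decide nothing for miR-33 knockout against WT or for the interaction (0 genes, 100 of 100 drawn splits, highest other 303). Over all 200 splits the highest other count for the interaction was 754. For the averaged miR-33 effect, 4 of all 200 splits within Ldlr genotype gave at least the real 152 genes. That share of 0.02 covers only a random grouping of all these libraries, since the 3 others gave more than the real split: 754, 303 and 174 genes. Splits that broke up the double and Ldlr knockout groups gave at most 3 genes. The share therefore does not exclude chance for the miR-33 grouping. A draw of 100 of the 200 splits missed all 3 that gave more (1 of 100 as large, highest other 1). The 3 mixed miR-33 knockout with WT libraries and kept the real double and Ldlr knockout groups with exchanged names, as the split with 303 for the interaction kept them with their own. They point to a structure of the samples that includes the difference between those groups (512 genes), and a count of this size did not need the real miR-33 knockout and WT groups, so the count is no evidence of a miR-33 effect with Ldlr intact.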

How the results depend on the processing

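Leaving out double knockout libraries a and b, the stromal covariate, array weights and the block were chosen after seeing the data; all other alternatives were planned. Cholesterol synthesis kept its direction and its call under every alternative run in 3 contrasts, with medians from 0.34 to 0.69 for double against Ldlr knockout, from -0.65 to -0.32 for Ldlr knockout against WT and from 0.36 to 0.76 for the interaction. For the averaged miR-33 effect its call ended with an estimated correlation (adjusted p = 0.0852), and for double against miR-33 knockout it gained one without double knockout libraries a and b (0.0891). Of 4941 alternative values for named genes, 3664 stayed on their side of the threshold, 1126 lost a call, 145 gained one and 6 reversed. Of 2830 for lists other than the main ones the counts were 2707, 69, 43 and 11. Both totals include genes or lists without a main call, which cannot lose one. Losses among those with a call were therefore more frequent than these totals show. Depth per gene is unknown, which limits low genes most. Where the construction of an alternative does not show it, the cause was not tested.

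Counts of called genes were 0 for miR-33 knockout against WT (A), 512 for double against Ldlr knockout (B), 88 for Ldlr knockout against WT (C), 309 for double against miR-33 knockout (D), 152 for the averaged miR-33 effect (M) and 0 for the interaction (I). With no filter on low values, where more genes are tested, they were 2, 916, 174, 0, 521 and 1, with 1 gene shared by A and B. With a mean FPKM of at least 5, where fewer are tested, B was 270 and M 38. Quantile normalization gave 1 in A and 1 shared gene, and no mean-variance trend gave 187 in D. Fits of only the groups compared, on fewer libraries, gave 7, 128, 1158 and 5 in A to D. Without double knockout libraries a and b they were 7, 13, 707, 2, 86 and 7 with 1 shared gene; the lone library left was assumed to vary like the other groups. With the stromal covariate B, C, D and M were 0; the score itself differed between groups. Array weights gave 13, 1927, 2560, 1390, 576 and 352, with 6 shared. Leaving out each library in turn gave 0 to 21, 116 to 1984, 1 to 366, 0 to 2277, 100 to 1051 and 0 to 306, with 0 to 21 shared genes, and an odds ratio near Ldlr in C of 0 to 2.48. With the number in the column names as a replicate block, B was 244, C 39 and D 0, M moved to 126, A and I stayed at 0, and no list call changed. These numbers do not pair the libraries: deviations from group means correlated at -0.284 to 0.148 over 18 pairs of the same number, over 0.1 in 3, and 0 libraries correlated best with their own number in every other group. The share of higher genes moved from 53.3% to 33.2% (no filter), 69.3% (mean FPKM of at least 5), 42.2% (block) and 24.2% (only these groups) in B; from 29.5% to 40.3% (pseudocount 5), 59.2% (no filter), 40.0% (quantile), 15.4% (block) and 39.9% (array weights) in C; from 34.3% to 0% (only these groups) and 100% (without libraries a and b) in D; and from 22.4% to 44.6% (array weights) in M.

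With the correlation estimated, list calls ended while medians stayed: fibroblast -1.46 in A, -2.77 in B and -2.07 in M, inflammatory activation -0.93 in B and -1.17 in D, and interferon response -1.08 in C and -1.02 in D. Without double knockout libraries a and b, inflammatory activation was -0.0512 in B and -0.0138 in I, where the test's direction turned, and interferon response was 0.0699 in B and 0.315 in I. With the stromal covariate, inflammatory activation was 0.00732 in B and 0.242 in M, interferon response 0.162, 0.509, 0.429 and 0.243 in A, B, M and I, and endoplasmic reticulum stress 0.198 in B and 0.196 in M. Under this covariate the interferon rises in B, M and I and the endoplasmic reticulum stress rises in B and M were called, and the other values were not. The 6 genes that turned did so there, and none was called: Ptgs2 0.111, Rnase6 -0.0431 and Trib3 0.0654 in B, and Enpp2 0.138, Ptgs2 0.183 and Sparc 0.0554 in M. The fibroblast list and its members were not tested under its score. After quantile normalization the lysosome list in C was 0.0794.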

Other observations

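The tests on Nnt and on other substrain genes in this part were chosen only after the result was seen, and the groupings of genes by separation were too.

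The small nucleolar RNAs Snord22 and Snora78, named after their values were seen, were low in the double knockout and also in Ldlr knockout library c. Snord22 was at 5752, 9163 and 1210.2 FPKM in Ldlr knockout libraries a, b and c and at 1692, 256 and 1665 in the double knockout, against 3742 to 4747 in WT and 6592 to 13950.0 in the miR-33 knockout. Snora78 was at 87.3 FPKM in Ldlr knockout library c, 110.4 ± 59.7 in the double knockout and 1134 ± 85.2 in the miR-33 knockout (SD, n = 3). The pseudogene Atp6v0c-ps2 followed the same libraries, at 147, 99.7 and 0.0805 FPKM in Ldlr knockout libraries a, b and c and at most 0.265 in the double knockout, against 39.7 to 142 in WT and 152 to 167 in the miR-33 knockout.

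The number of genes whose 3 libraries of a group all lay below or all above the other 9 was 404 and 388 for the Ldlr knockout, 285 and 376 for the double knockout, 133 and 121 for WT, and 52 and 72 for the miR-33 knockout, where chance gives 49.3 (0.455%) in each direction.

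Nnt, a mitochondrial enzyme with a known deletion in a common C57BL/6 substrain, was at 6.42 to 6.62 FPKM in WT and at 10.1 to 18.2 in the other 9 libraries. Its interaction of -0.67 (SE 0.22; limma, unadjusted p = 0.0109) decides nothing about separate, additive effects of miR-33 and Ldlr loss, since Nnt was picked because WT alone stood apart. A substrain difference between the WT mice and the other 3 groups could account for it, and it stays open: 0 of 3 other substrain genes (Wdfy1, Ide and Fgfbp3) parted WT from the other 9 libraries, but Fgfbp3, at 0.513 to 1.24 FPKM in those 9, was too low to count, and genotype and substrain cannot be told apart here. Wdfy1 was at 18.8 to 21.4 FPKM in WT, 34.6 to 36.8 in the miR-33 knockout and 29.3 to 33.3 in the Ldlr knockout, while the double knockout libraries were at 19.0, 24.3 and 39.1. Ide parted the libraries by Ldlr genotype instead. It was at 10.35 to 11.47 FPKM in WT and 10.2 to 11.11 in the miR-33 knockout. In the Ldlr knockout it was at 14.6 to 15.93 and in the double knockout at 16.95 to 23.34. A substrain difference that goes with Ldlr genotype therefore stays open as well, for both comparisons of Ldlr loss.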
